A study of Rattus norvegicus with 11 samples.

How the data were processed

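Gene expression was measured in cultured rat cortical neurons on 2-colour oligonucleotide arrays. Per the labels' protocols, neurons were plated at 1500 cells per mm2, kept in a mixed serum and Neurobasal medium and treated at 9 to 11 days in vitro. Treated RNA was compared with RNA of cultures given the solvent DMSO for the same time, after linear RNA amplification and labelling with Cy5 and Cy3. The labels give 11 samples in 9 groups. Bicuculline with 4-aminopyridine (Bic/4AP) for 8 h had 3 samples, numbered 1 to 3, and the other 8 groups had 1 sample each. Nothing in the labels says whether the 3 came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

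Each sample had 2 scanner files of 28800 spots. The deposited spot intensity values were the brightness of the foreground and of the local background at 635 and 532 nm, on a linear scale and not normalized, per the file headers. The deposited percent columns gave the share of saturated pixels of a spot, per the file headers, and the deposited flag score was 0 or -50. The rule behind the flags, the scanner and the software were not given in the sources used here. The authors' value table held 1 log2 ratio per probe and sample. Set against the scanner files, it followed the first file minus the second, with correlations of 0.809 to 0.991 across probes, slopes of 0.998 to 1.36 and column medians from -0.0077 to 0.014. Its scale and centring are therefore close to log2 and 0, while its direction, normalization and filter are not stated.

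The labels name Cy5 for treated and Cy3 for DMSO RNA and do not describe the second file. Spike-in control spots Y5 to Y8 changed sign between the files in 44 of 44 pairs of spot and sample, so the 2 files were read as a dye swap. The first file was taken as the labelled one. The spike-ins show a swap but not which file is the labelled one. Y5 was higher in red of the first file in 4 of 11 samples (Bic alone, MK801, nifedipine and Bic/4AP replicate 2) and lower in the other 7. Among the single samples, those with Y5 higher were also those that kept most of the Bic/4AP response, while the Bic/4AP replicates fell on both sides. With the first file as the labelled one, the ratios of replicate 2 correlated across genes with those of replicates 1 and 3 at 0.72 and 0.84. Among the labels and spike-ins, only its number points to the first file as the labelled one. The authors' table, which subtracts the second file from the first, shares this order but does not test it, since its direction is not stated. By the labels and files, the direction of treated over DMSO is likely but not settled, and the other order in all samples would turn the sign of every ratio and difference. Immediate early transcription factors, which firing induces, had list medians of 1.649 in Bic alone, 1.211 with nifedipine, 0.605 after the pulse, 0.573 at 2 h and 0.486 with MK801. They rose in Bic/4AP 8 h as well. The other order would make them fall, which argues against it for these samples. The medians with EGTA, TTX and both blockers (0.209, -0.066 and -0.092) do not tell. Within a file number, the lowest correlation between samples over all probes was 0.028 for the first files and -0.019 for the second.

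Values were computed in R 4.3.3 with limma 3.58.1, with the R packages data.table (version 1.17.8) and jsonlite (version 2.0.0) for reading and writing. Foreground means were corrected with the local background medians by normexp with an offset of 50 and normalized by print-tip loess over 48 blocks of 600 spots, in which control spots had weight 0. The sign of the second file was turned, spots of a probe were averaged, and the 2 files of a sample were averaged to 1 replicate. The 1706 control or blank spots were left out, and saturated spots were kept. A probe entered the tests if both files of a sample gave it flag 0 in at least 3 samples. Normexp fitted background means from -496 to 25, because up to 28.3% of the gene spots of an array, and 5.36% at the median, lay below their local background. The offset that acted on the arrays was therefore 25 to 546 instead of 50, with means per sample from 35 with EGTA to 482 in Bic/4AP replicate 1. This shrinks the ratios of dim genes, and by different amounts on different arrays. The setting was kept because it was fixed before the data were examined, and a common floor and offset was added as an alternative after seeing the data.

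The files named 14981 of 26962 gene probes. Of these names, 8830 matched a current symbol and 5218 a synonym in a RefSeq table of the rat assembly GRCr8, used for names only, and 933 kept the name in the files. A few names had been turned into dates and were kept as they stand. The tests covered 21318 features from 23627 found probes: 11012 named genes, each by its brightest probe, and 10306 unnamed probes. Of the named genes, 1806 had several probes, and disagreement is stated where such a gene is named. Fos, Homer1 and Nptx2 were not analysed here. Per array, 55.6% to 93.9% of gene spots were found, and the foreground was 2.08 to 24.8 times the background in red and 1.8 to 8.29 times in green. The number of arrays limits the precision.

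A single limma model of group means was fitted to all samples with eBayes and Benjamini-Hochberg adjustment over all features, with calls at an adjusted p under 0.05. Bic/4AP 8 h was tested against 0. DMSO RNA was measured only as the other channel, so any spread of the control enters only through the ratios and was not estimated apart. Each other condition was tested against Bic/4AP 8 h, and MK801 against nifedipine. The 8 single samples add no residual degrees of freedom. The spread comes from the 3 Bic/4AP samples, with 2 residual and 3.95 prior degrees of freedom, and each lone sample is assumed to vary like them. How much of the response was present in a condition was described by the median log2 ratio there of the genes called in Bic/4AP 8 h. As a benchmark, each Bic/4AP sample was read on as many genes chosen from the other samples only. Errors are SD over the 3 samples or standard errors of the fit, as stated. A probe counted as above background when its foreground exceeded the local background by 2 of its SD. Where one channel missed this on every array of a group, the fold is given as a bound, from the brighter channel's mean against the higher of the dim probe's own signal and the lowest signal above background, per channel after loess and Aquantile.

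The 26 gene lists fixed before the data were examined covered immediate early transcription factors, activity-regulated effectors, MAP kinase phosphatases and feedback regulators, neuropeptides and granule proteins, growth factors, glutamate receptors and scaffolds, GABA genes, potassium, sodium and calcium channels, presynaptic machinery, cytoskeleton, cholesterol and fatty acid synthesis, glycolysis, oxidative phosphorylation, heat shock and endoplasmic reticulum stress, apoptosis, proteasome, ribosomal proteins, proliferation, the circadian clock, and markers of neurons, astrocytes, oligodendrocytes, microglia and endothelial, mural and fibroblast cells. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, which asks whether the genes of a list move, on balance, one way and does not compare them with other genes. The estimated correlation is judged on the 2 residual degrees of freedom. After adjustment over 26 lists it could hardly call any list, so failing it does not undo a call. Where a replicate was left out, values were missing or files were taken as arrays, lists were tested with cameraPR instead, on the moderated t statistics. A list call gained or lost under those settings cannot be told apart from the change of test. The lists share members, such as Bdnf and Inhba in effectors and growth factors, or Rgs2 in effectors and phosphatases. Calls of lists that overlap are therefore not separate findings. Named genes were chosen by a rule fixed at the same time. It takes the 12 largest rises and falls among called genes with 1 sign in all 3 samples, up to 4 members of each list with the largest change, the 5 largest differences in each direction for each single sample, up to 5 genes per direction over 2-fold in both files of a single sample, and a fixed set of activity-regulated and interneuron genes. Some genes that this rule takes are not reported here.

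The model was tested on simulated data over 21318 genes. For Bic/4AP 8 h against DMSO it recovered 35.8% of changes of 0.5, 92.5% of changes of 1 and 100% of changes of 2 on the log2 scale, with 7 false calls. For the TTX sample against Bic/4AP 8 h it recovered 0%, 23.9% and 83.3%, with 0 false calls. The simulation drew independent noise with the same SD per gene in every sample and had no array or culture effects. It thus assumed that a lone sample varies like the Bic/4AP 8 h samples and cannot test this. Simulated responses kept in full, by 0.5 and by 0 gave 101%, 50.8% and -3.55% of the held-out value. Alternatives covered the background correction, the normalization within and between arrays, the authors' table, filters, single files, files as arrays with the sample as a random block, the prior, the threshold and leaving out each Bic/4AP sample. The median foreground, a dye term, leaving out probes that follow the spike-in mix and the common floor and offset were added after seeing the data. Slide and scan date were not used here.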

Results

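The data compared gene expression in cultured rat cortical neurons after pharmacological changes of firing with that in cultures given the solvent DMSO. Bicuculline (Bic, 50 µM) blocks GABA-A receptors and 4-aminopyridine (4AP, 5 µM) blocks potassium channels, and per the labels these treatments set off bursts of action potentials, which TTX and EGTA abolished and MK801 and nifedipine altered. Bic/4AP for 8 h was measured in 3 samples. There was 1 sample each of Bic alone for 8 h, Bic/4AP with 1 µM tetrodotoxin (TTX, which blocks sodium channels), with 4 mM EGTA (which chelates extracellular calcium), with 10 µM MK801 (an NMDA receptor blocker), with 5 µM nifedipine (an L-type calcium channel blocker), with both MK801 and nifedipine, Bic/4AP for 2 h, and a 2 h pulse of Bic/4AP followed by 6 h after its removal. Each sample was hybridised on a pair of dye-swapped arrays against its DMSO control. Between 14309 probes (Bic/4AP replicate 1) and 24165 probes were found in both files of a sample. Values are log2 ratios of treated over DMSO unless said otherwise. This direction takes the first file of each sample for the labelled one. It is likely, as immediate early genes rise under Bic/4AP in it, but the labels do not settle it. The single samples have no replicate check. No sample had a blocker without Bic/4AP, so an agent's own effect cannot be told apart from a lost response. Since EGTA, MK801 and nifedipine also changed the bursts, a need for calcium cannot be told apart from changed firing.

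The first comparison asked which genes change with 8 h of Bic/4AP. The largest rises were in Gprc5a, a retinoic acid-induced receptor (5.33 ± 0.40, SD, n = 3, as for the values that follow), Serpinb2, a serpin protease inhibitor (5.15 ± 0.73), the neurotrophin Bdnf (4.92 ± 0.34), and the peptide or granule genes Adcyap1 (4.18 ± 0.41), Scg2 (4.10 ± 0.29), Crh (3.95 ± 0.44) and Penk (3.29 ± 0.55). The cAMP-response regulator Crem (3.72 ± 0.59), Porf1 (3.65 ± 0.25) and the chemokine Ccl2 (3.44 ± 0.77) also rose. Gem, a small GTPase, and Npas4, an activity-dependent transcription factor, were not well above background in DMSO on any array and rose at least 9.18-fold and at least 8.93-fold. The largest falls were smaller in the direction taken, while with the other file order the largest rises would be the smaller ones. Gucy1a1, a subunit of soluble guanylate cyclase, fell by 1.70 ± 0.07, Fgfbp1 by 1.65 ± 0.51, Camsap3 by 1.41 ± 0.25, Grb14 by 1.38 ± 0.40, the kinase Map2k6 by 1.35 ± 0.12, Klf7 by 1.31 ± 0.43 and Ephb6 by 1.20 ± 0.49, and Adgrb3, Pgap4, Spire2, Gpr37 and RGD1309058 fell by 1.12 to 1.17.

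In the limma model, 1868 of 21318 features were higher and 1271 lower at an adjusted p under 0.05, of which 345 and 43 changed at least 2-fold. Each named rise and fall had 1 sign in all 3 samples. The counts rested on the replicates and on the background correction: they were 2641 higher and 2193 lower without replicate 1, 986 and 485 without replicate 2, 393 and 53 without replicate 3, 707 and 255 with the local background subtracted and a common floor and offset, 116 and 11 with plain subtraction, and 1138 and 759 in the authors' deposited table. Of 34 named genes, 10 were no longer called without replicate 3, among them Adgrb3, Ephb6, Grb14, Klf7, RGD1309058 and Spire2, 19 with plain subtraction, and 6 with a common floor and offset, among them Ephb6, Grb14 and RGD1309058. Other probes of Adgrb3 and Penk gave -0.09 and 0.51, neither of them called.

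Camera called 9 lists upward, 5 of them with adjusted p values of 3e-14 for immediate early transcription factors, 3.6e-19 for activity-regulated effectors, 4e-10 for neuropeptide and granule genes, 3e-04 for MAP kinase phosphatases and feedback regulators and 0.001 for growth factors, but adjusted p = 0.47 for each of these 5 with an estimated correlation. Of 29 measured immediate early transcription factors 20 were higher and 0 lower (22 higher and 1 lower when adjusted over the list alone), among them Nr4a3 (2.99 ± 0.36), Nr4a1 (2.99 ± 0.65), Egr1 (2.15 ± 0.43), Junb (2.11 ± 0.41) and Fosb (0.78 ± 0.37). Of 37 activity-regulated effectors 26 were higher and 0 lower (30 and 0 adjusted over the list alone), including Arc, which encodes a synaptic plasticity protein (3.14 ± 0.45), Inhba (3.03 ± 1.10) and Syt4 (2.60 ± 0.11). Of 32 neuropeptide and granule genes 18 were higher and 0 lower (21 and 0 adjusted over the list alone), with Vgf at 2.29 ± 0.36 and Sst at 0.97 ± 0.42. Npy, at 0.47 ± 0.43, did not pass (adjusted p = 0.11). Of 25 MAP kinase phosphatases and feedback regulators 10 were higher and 0 lower (11 and 1 adjusted over the list alone), led by Rgs2 (3.11 ± 0.33), Dusp1 (2.55 ± 0.35) and Dusp5 (2.40 ± 0.21). Of 30 growth factor genes 12 were higher and 2 lower (14 and 2 adjusted over the list alone), with Fgf9 at 2.12 ± 0.31 and Bmp2 at 1.82 ± 0.41.

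Fry, which does not set a list against other genes, gave these 5 lists adjusted p values of 0.039, 0.028, 0.039, 0.028 and 0.041 in the order given. Fosb, Sst, Inhba and Gad1 (0.71 ± 0.45, adjusted p = 0.039) were no longer called without replicate 3. With a common floor and offset Fosb, Sst and Gad1 were not called either, nor was Gad1 without replicate 2 (adjusted p = 0.053), nor Fosb in the authors' deposited table (adjusted p = 0.061).

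Camera called 4 further lists upward, none of which passed with an estimated correlation, a check that could hardly call any list. Heat shock and endoplasmic reticulum stress had 8 of 38 genes higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 0.001, and adjusted p = 0.47 with an estimated correlation), with Ddit3 at 0.53 ± 0.06 and Xbp1 at 0.53 ± 0.01. Endothelial, mural and fibroblast markers had 4 of 16 higher and 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 0.0011, and adjusted p = 0.47 with an estimated correlation), led by the collagen crosslinker Lox (0.89 ± 0.47) and Postn (0.79 ± 0.54). With cameraPR both calls were lost without replicate 2 (adjusted p = 0.11 and 0.13), the second also without replicate 3 (0.058) and the first also in the authors' deposited table (0.063). Fry gave them 0.075 and 0.09. Presynaptic genes had 11 of 41 higher and 1 lower, likewise adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.53 with an estimated correlation, fry 0.068), with the vesicular glutamate transporter Slc17a6 at 3.19 ± 0.48. Circadian clock genes had 7 of 16 higher and 1 lower, likewise adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.47 with an estimated correlation, fry 0.028), led by Nfil3 (2.55 ± 0.31) and Rorb (1.47 ± 0.41), and the call was lost over the probes found in all samples (0.11). In limma Ddit3, Xbp1 and Rorb were not called without replicate 3 (adjusted p = 0.079, 0.07 and 0.056), nor were Lox and Postn without replicate 2 (0.088 and 0.16) or replicate 3 (0.13 and 0.25). Nfil3 is also an immediate early factor on its list, and Per1 and Per2 of the clock are also effectors. The call of the clock is therefore not separate from theirs.

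The other 17 lists had camera adjusted p values from 0.052 to 0.89. Their counts are given as higher and lower of those measured, with the counts adjusted over the list alone in parentheses. Pan-neuronal markers counted 10 and 3 of 24 (10 and 3), with the neurofilament Nefl at 2.21 ± 0.69 and the GABA-synthesizing enzyme Gad2 at 1.05 ± 0.39. Glutamate receptors and scaffolds counted 10 and 3 of 39 (11 and 5), with the scaffold Dlg2 at 1.36 ± 0.20. The cytoskeleton counted 9 and 2 of 39 (10 and 3), calcium channels and signalling 8 and 1 of 53 (8 and 4), with the calcineurin regulators Rcan2 at 1.75 ± 0.38 and Rcan1 at 1.28 ± 0.05, potassium channels 6 and 3 of 43 (7 and 3), sodium channels 1 and 1 of 10 (2 and 2), and GABA genes 6 and 2 of 27 (7 and 2). Cholesterol and fatty acid synthesis counted 5 and 4 of 27 (5 and 5), glycolysis 3 and 0 of 27 (5 and 0), and oxidative phosphorylation 1 and 0 of 36 (0 and 0). Apoptosis regulators counted 2 and 6 of 33 (2 and 8), proliferation 0 and 1 of 20 (0 and 0), and the proteasome, with 26 genes, and ribosomal proteins, with 63, 0 and 0 (0 and 0) in limma. Astrocyte markers counted 2 and 2 of 21 (2 and 3), oligodendrocyte markers 1 and 0 of 16 (0 and 0) and microglia markers 1 and 0 of 18 (3 and 0), the last of these Tlr4 (1.27 ± 0.34). Gad2 and Tlr4 were not called without replicate 3 (adjusted p = 0.068 and 0.056 in limma) or with a common floor and offset (0.16 and 0.077). The oligodendrocyte list had a median and a mean of -0.01, while camera gave it an upward sign. CameraPR, the test used where a replicate was left out, called pan-neuronal markers without replicate 1 (adjusted p = 3.3e-05) and without replicate 3 (0.021). It called the cytoskeleton likewise (0.0043 and 0.028), and microglia and proliferation without replicate 1 (0.00012 and 0.00032). These calls cannot be credited to the replicate left out, since the test differed too.

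**Figure D1:**
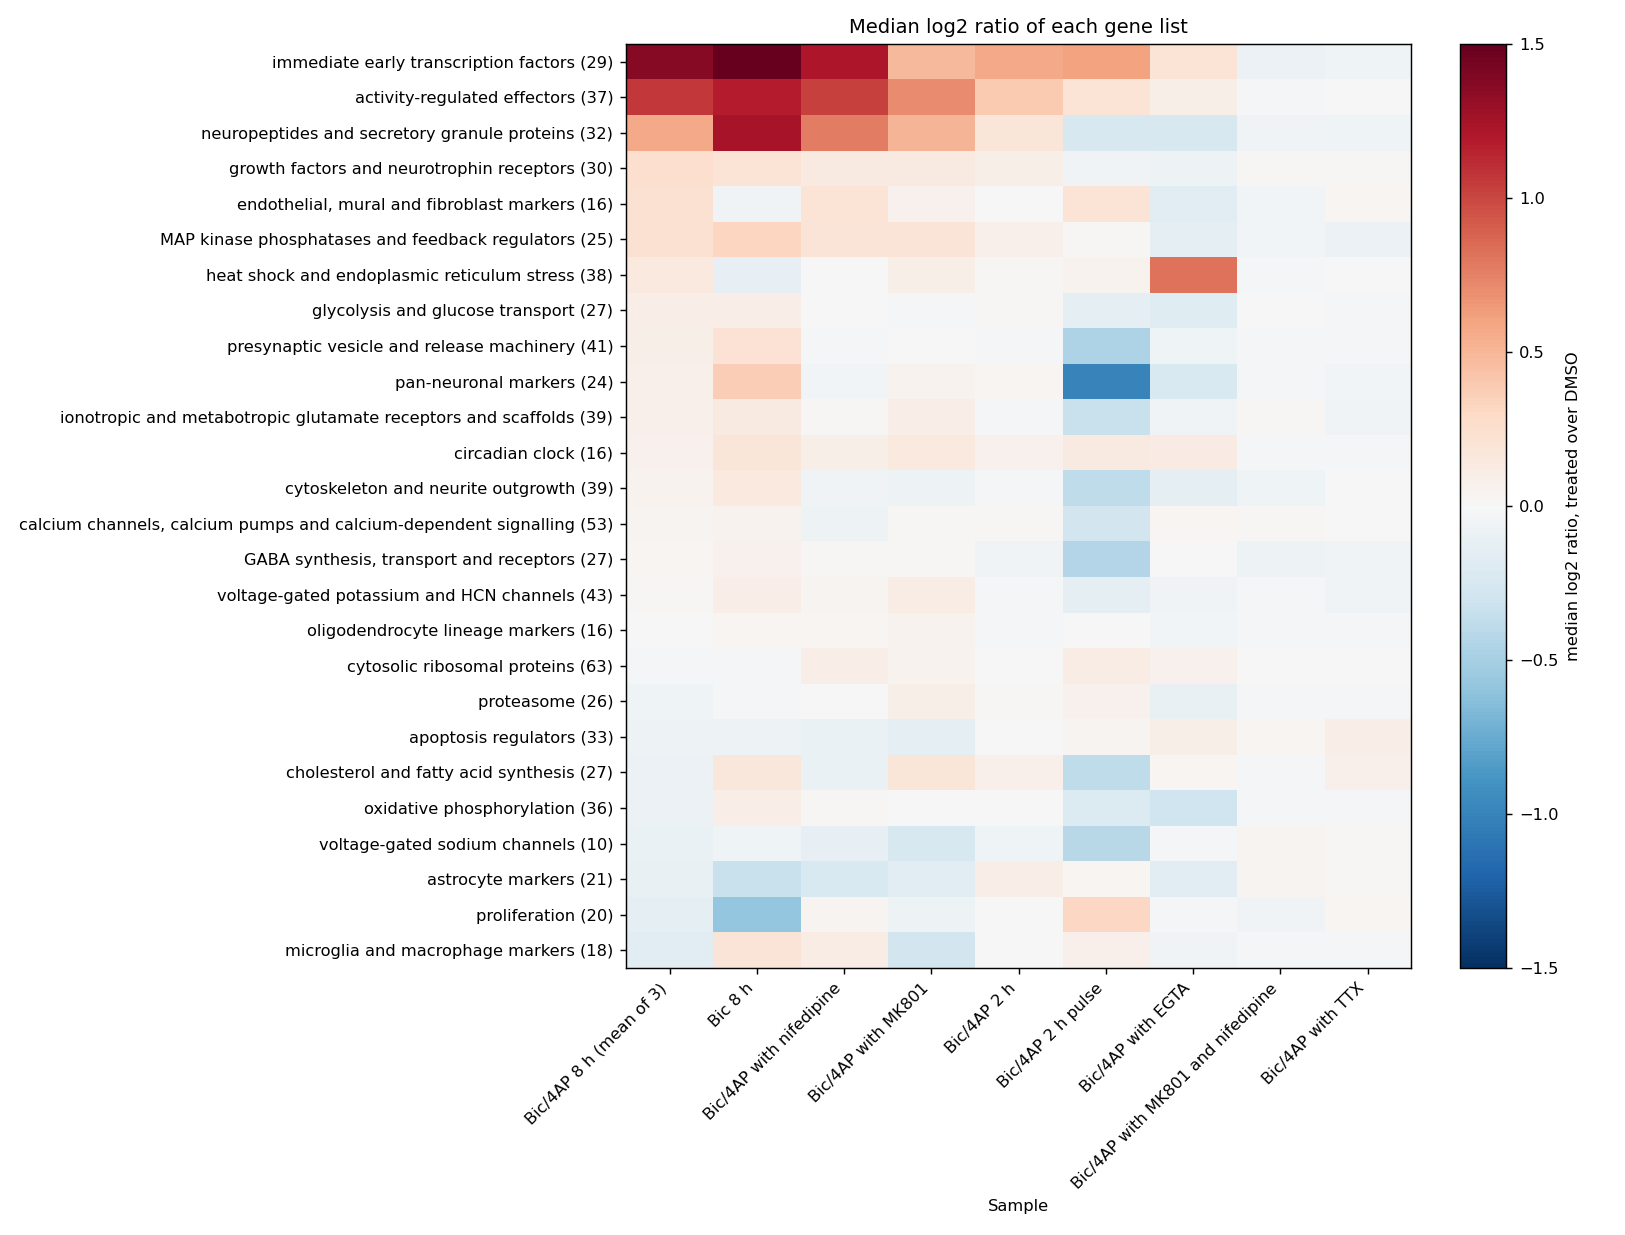
Median log2 ratio of treated over DMSO for each gene list (vertical axis, number of measured genes in parentheses) in each condition (horizontal axis), with the mean of 3 samples for Bic/4AP 8 h and 1 sample elsewhere. Immediate early transcription factors have a median of 1.37 under Bic/4AP 8 h and -0.07 with TTX, and pan-neuronal markers one of -1.01 after the 2 h pulse.

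How far the same response was present in the other conditions was read from the genes called in Bic/4AP 8 h. Held-out Bic/4AP samples gave a median of 0.513 ± 0.042 for the raised and -0.36 ± 0.034 for the lowered genes (SD, n = 3). Bic alone gave 0.58 and -0.432, nifedipine 0.442 and -0.464, and MK801 0.196 and -0.25. Medians were 0.105 and -0.0826 at 2 h, 0.0628 and -0.029 with EGTA, 0.0398 and -0.207 after the pulse, 0.0253 and 0.0148 with MK801 and nifedipine together, and 0.000979 and 0.0271 with TTX. Of the 345 genes raised at least 2-fold, 287 were still raised 2-fold in Bic alone, 263 with nifedipine, 94 with MK801, 55 at 2 h, 41 after the pulse, 14 with EGTA and 0 with TTX or with both blockers. With plain subtraction of the background, where fewer genes were called, the held-out medians were 2.08 and -1.19, Bic gave 2.12, nifedipine 1.63, MK801 0.809 and TTX -0.0719. Medians of the raised genes also changed with the genes called when a replicate was left out. Without replicate 2, where fewer genes were called, they were 0.881 in Bic alone, 0.718 with nifedipine, 0.32 with MK801 and 0.171 at 2 h. Without replicate 3, where 393 raised genes were called, they were 1.39, 1.11, 0.438 and 0.313. These settings have no held-out value, so their medians cannot be set against 0.513. The pulse median was 0.0191 without replicate 1. Those of the lowered genes became -0.81 in Bic alone, -0.912 with nifedipine, -0.459 with MK801, -0.216 at 2 h, -0.193 with EGTA and -0.604 after the pulse without replicate 3, -0.0674 with EGTA and -0.362 after the pulse without replicate 2, and -0.0441 at 2 h, -0.0708 with EGTA and -0.0971 after the pulse without replicate 1. With TTX and with both blockers, medians of raised and of lowered genes lay between -0.0185 and 0.0332 when 1 replicate was left out.

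**Figure D2:**
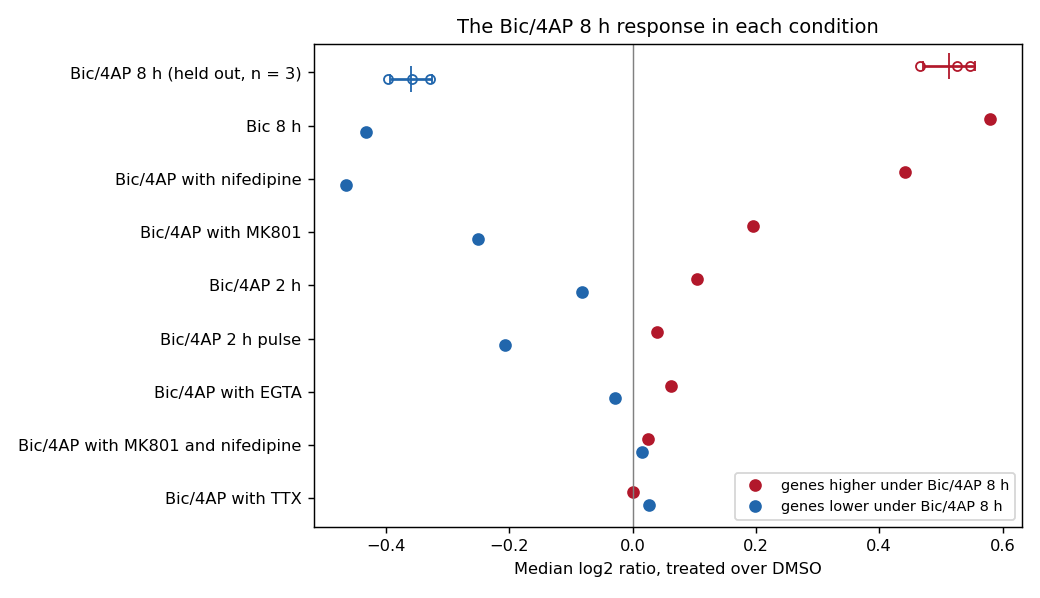
Median log2 ratio of treated over DMSO (horizontal axis) of the genes higher (red) and lower (blue) under Bic/4AP 8 h, in each condition (vertical axis). Filled points are single samples, open points the 3 held-out Bic/4AP samples and bars their mean ± SD, and TTX lies at 0.000979 and 0.0271 against held-out means of 0.513 and -0.36.

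The TTX sample asked whether the response is present with sodium channels blocked, and the sample with MK801 and nifedipine whether it is with both routes of calcium entry blocked. With TTX, Serpinb2 stood at -0.14, Bdnf at -0.12, Adcyap1 at -0.70 and Scg2 at -0.55, and Gprc5a was not well above background in either channel. With both blockers the same order of genes gave -0.10, 0.22, -0.27 and -0.07, and Gprc5a -0.06. Gucy1a1, which fell under Bic/4AP, stood at -0.23 and 0.18, and Camsap3 at 0.02 and -0.08. The potassium channel gene Kcng1 (-1.07 ± 0.26 in Bic/4AP 8 h, not called without replicate 3, adjusted p = 0.055 in limma) was 0.49 with TTX. The median of the immediate early transcription factors was -0.07 and -0.09.

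Against Bic/4AP 8 h, 19 features were higher and 180 lower with TTX, and 18 and 190 with both blockers (limma, adjusted p under 0.05, each lone sample assumed to vary like the 3). Of 29 immediate early factors 10 and 12 were lower (18 and 18 adjusted over the list alone, camera adjusted p = 8.8e-17 and 1.9e-16, and adjusted p = 0.41 and 0.47 with an estimated correlation), and of 37 effectors 11 and 11 (22 and 25 adjusted over the list alone, camera adjusted p = 4.8e-19 and 1.1e-20, and adjusted p = 0.41 and 0.47 with an estimated correlation). In this and the later comparisons, further lists that camera called are given as members called higher and lower of those measured, the same counts adjusted over the list alone, and camera's adjusted p. With TTX camera called 7 more lists lower. They were neuropeptides (0 and 6 of 32, 0 and 15, 3.2e-11), MAP kinase phosphatases (0 and 5 of 25, 0 and 10, 1.1e-06) and growth factors (0 and 3 of 30, 2 and 8, 0.0043). The others were presynaptic genes (0 and 2 of 41, 0 and 6, 0.0066), the circadian clock (0 and 2 of 16, 1 and 5, 0.017), glutamate receptors (0 and 1 of 39, 2 and 8, 0.017) and heat shock (0 and 0 of 38, 0 and 1, 0.025). Their adjusted p was 0.41 or 0.54 with an estimated correlation. Heat shock was not called without replicate 2 (0.21), without replicate 3 (0.12) and under 7 other settings (0.054 to 0.22). Glutamate receptors were not called without replicate 2 (0.18) and in the authors' deposited table (0.38), nor was the clock over the probes found in all samples (0.16). With both blockers it called 9 more lists lower. They were neuropeptides (0 and 6 of 32, 0 and 12, 8e-11), MAP kinase phosphatases (0 and 5 of 25, 0 and 10, 1.9e-05), growth factors (0 and 3 of 30, 1 and 7, 0.0022) and heat shock (0 and 1 of 38, 0 and 1, 0.007). The others were presynaptic genes (0 and 2 of 41, 0 and 3, 0.012), the clock (0 and 3 of 16, 0 and 5, 0.012), the cytoskeleton (0 and 1 of 39, 0 and 4, 0.012), pan-neuronal markers (0 and 1 of 24, 2 and 8, 0.013) and endothelial, mural and fibroblast markers (0 and 0 of 16, 0 and 0, 0.017). Their adjusted p was 0.47 or 0.51 with an estimated correlation. Without replicate 2 the calls of heat shock (0.094), the cytoskeleton (0.17), pan-neuronal markers (0.05) and endothelial, mural and fibroblast markers (0.17) were lost, the last of these also without replicate 3 (0.099). Other settings ended calls of these 4, of presynaptic genes and of the clock (0.052 to 0.11). Leaving out replicate 1 gave 1911 features with TTX and 1980 with both blockers, leaving out replicate 2 gave 144 and 116, leaving out replicate 3 gave 0 and 0, both background subtractions gave 0 and 0, and the authors' deposited table gave 58 and 42. With TTX 0 features were over 2-fold higher in both files and 10 over 2-fold lower. Golga1 (-1.68), Or1e23 (-1.61), Il9 (-1.45) and Or2d3c (-1.41), among the latter, belong to 13 probes whose ratio followed the spike-in mix.

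The MK801 and nifedipine samples asked how much of the response is present with either route of calcium entry blocked alone. With MK801, Bdnf (4.25), Arc (3.67), Penk (3.50), Ccl2 (3.17) and Vgf (2.59) remained high over DMSO, and Gprc5a at least 11.9-fold. Syt4 stood at -0.09, Lrrn3 at -0.11 and Epha7 at 0.36, against 2.60 ± 0.11, 1.76 ± 0.16 and 2.16 ± 0.16 without the blocker, and Npas4 and the secreted factor Stc1 were not well above background in either channel. These 5 were among 20 features called lower than in Bic/4AP 8 h, where 6 were higher. Called higher were Prl7d1, Kcnmb3 and Pcdh18, each above background in 1 of 2 treated files, at least 3.19-fold, at least 2.74-fold and at least 2.47-fold over DMSO. In the first file alone the differences of Kcnmb3 and Pcdh18 from Bic/4AP 8 h were -0.17 and -0.57, and that of Pcdh18 was -0.44 with the median foreground. Without replicate 2, Stc1, Prl7d1, Kcnmb3 and Pcdh18 were not called (adjusted p = 0.057, 0.058, 0.071 and 0.082 in limma). With nifedipine Ccl2 stood at 5.14, Bdnf at 5.07, Scg2 at 4.43 and Adcyap1 at 4.27, and Serpinb2 and Gprc5a at least 22.8-fold and at least 18.5-fold over DMSO. The only called difference from Bic/4AP 8 h was Nedd1, at least 7.53-fold lower than DMSO, where its treated channel was not above background.

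The count of differences from Bic/4AP 8 h was 26 with MK801 and 1 with nifedipine. Camera called immediate early factors lower with MK801 (1 of 29 lower, 7 adjusted over the list alone, adjusted p = 0.00014, and adjusted p = 0.64 with an estimated correlation), and with nifedipine effectors lower (0 of 37 called, 1 lower adjusted over the list alone, adjusted p = 0.037, and adjusted p = 0.75 with an estimated correlation). The first call was lost with scaled ratios (0.076), with plain subtraction (0.7) and in the authors' deposited table (0.16), and the second without replicate 1 (0.15) and under 6 other settings (0.057 to 0.75). With MK801 camera also called effectors (0 and 2 of 37, 1 and 9, 0.00014) and presynaptic genes (0 and 1 of 41, 0 and 2, 0.029) lower. Higher were cholesterol and fatty acid genes (0 and 0 of 27, 2 and 0, 0.024) and the proteasome (0 and 0 of 26, 0 and 0, 0.029). Each of these 4 had an adjusted p = 0.64 with an estimated correlation. With nifedipine it called ribosomal proteins higher (0 and 0 of 63, 0 and 0, 0.0029, and adjusted p = 0.75 with an estimated correlation). Of these calls, effectors were lost with scaled ratios (0.22) and plain subtraction (0.36) and presynaptic genes under 4 settings (0.051 to 0.4). Cholesterol genes were not called without replicate 1 (0.053) and under 3 other settings (0.051 to 0.55), nor was the proteasome without replicate 2 (0.3) and under 4 other settings (0.063 to 0.7). Ribosomal proteins were not called without replicate 2 (0.13), in the first file alone (0.062) and with plain subtraction (0.45). Without replicate 1 the counts were 970 and 1293, without replicate 2 27 and 0, without replicate 3 0 and 0, and with either background subtraction 0 and 0. Set directly against nifedipine, MK801 gave 0 calls in limma, with 1296 features at an unadjusted p under 0.05 against 1066 by chance. Klf10 differed by 2.28 ± 0.20 (standard error of the fit), with an adjusted p of 0.058. Without replicate 1 there were 643 calls, and 12 with no background correction. Camera called 4 lists in this comparison, each with an adjusted p = 0.95 with an estimated correlation and 0 members called. Lower with MK801 were immediate early factors (2 higher and 6 lower of 29 adjusted over the list alone, median difference -0.21, adjusted p = 0.0041), neuropeptide and granule genes (0 higher and 3 lower of 32 adjusted over the list alone, -0.11, 0.012) and microglia markers (0 and 0 of 18 adjusted over the list alone, -0.44, 0.005). Higher were cholesterol and fatty acid genes (0 and 0 of 27 adjusted over the list alone, 0.26, 5.7e-05), with Fdft1, which encodes squalene synthase, at 0.09 and -0.61. Plain subtraction ended these calls (0.92, 0.16, 0.27 and 0.15). The first and second were also lost with scaled ratios (0.51 and 0.81), with a common floor and offset (0.081 each), over the probes found in all samples (0.15 and 0.099) and in the authors' deposited table (0.07 and 0.12), and the second in the second file alone (0.19).

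**Figure D3:**
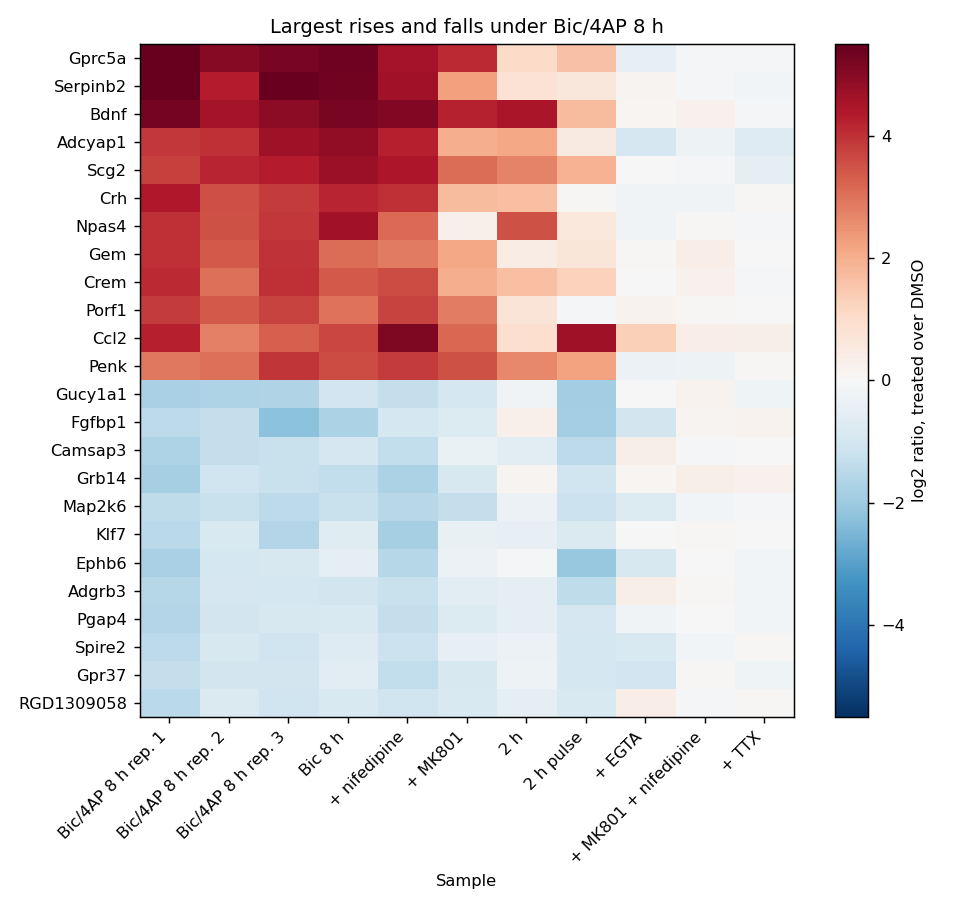
Log2 ratio of treated over DMSO (colour) of the 12 largest rises and 12 largest falls under Bic/4AP 8 h (vertical axis) in each sample (horizontal axis), with the 3 Bic/4AP 8 h replicates first and genes not well above background drawn at their measured ratios. Bdnf is 4.25 with MK801, 4.48 at 2 h and -0.12 with TTX.

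The EGTA sample asked how much of the response is present with extracellular calcium chelated. Bdnf stood at 0.09, Scg2 at -0.02, Adcyap1 at -0.91 and the G protein regulator Rgs2 at -1.07, and Serpinb2 was not well above background in either channel. Some genes stayed high, with Egr1 at 1.90 and Ccl2 at 1.30. Of the heat shock and endoplasmic reticulum stress list, Sdf2l1 stood at 2.62 over DMSO, the heme oxygenase Hmox1 at 2.40, Creld2 at 2.24 and the disulfide isomerase Pdia4 at 1.93. Snorc (2.59), Sh2d3c (2.40), Mical2 (2.33), the zinc finger factor Klf10 (2.15) and the caspase Casp4 (1.99) were high too, while Ahsp (-2.31), Wdr55 (-1.73), the glycolytic enzyme Tpi1 (-1.70), Scrg1 (-1.60) and Anp32a (-1.58) were low.

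Against Bic/4AP 8 h, 1293 features were higher and 1195 lower with EGTA. Of the heat shock and stress list 19 of 38 were higher and 0 lower (23 and 2 adjusted over the list alone, camera adjusted p = 3.2e-07, and adjusted p = 0.5 with an estimated correlation). Of apoptosis regulators 7 of 33 were higher and 0 lower, likewise adjusted over the list alone (camera adjusted p = 0.0076, adjusted p = 0.5 with an estimated correlation, and 0.1 over the probes found in all samples). Of 32 neuropeptide genes 16 were lower and 0 higher (22 and 0 adjusted over the list alone, camera adjusted p = 1e-10, and adjusted p = 0.5 with an estimated correlation). Camera called 10 more lists lower. They were effectors (0 and 13 of 37, 4 and 17, 4.2e-05), the cytoskeleton (0 and 9 of 39, 0 and 10, 0.00042), immediate early factors (2 and 13 of 29, 4 and 16, 0.00079), MAP kinase phosphatases (2 and 6 of 25, 2 and 8, 0.0012) and growth factors (1 and 8 of 30, 1 and 11, 0.0013). The others were oxidative phosphorylation (0 and 4 of 36, 0 and 4, 0.0013), pan-neuronal markers (1 and 5 of 24, 1 and 9, 0.0013), endothelial, mural and fibroblast markers (0 and 1 of 16, 0 and 6, 0.0015), presynaptic genes (1 and 5 of 41, 1 and 9, 0.0071) and glycolysis (0 and 5 of 27, 0 and 6, 0.0096). These 10 had an adjusted p of 0.5 to 0.57 with an estimated correlation. The total of 2488 became 5479 without replicate 1, 1032 without replicate 2, 25 without replicate 3, 1601 with no background correction, 686 in the authors' deposited table, 580 with ratios scaled between arrays and 0 with either background subtraction. Other probes of Casp4 gave 0.04 to -0.79 in Bic/4AP 8 h, where the named one gave -0.91.

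The sample with Bic alone asked what 4AP adds. Gprc5a (5.33), Serpinb2 (5.31), Bdnf (5.23), Adcyap1 (4.89) and Scg2 (4.76) were high over DMSO, and none of these 5 passed the test of a difference from Bic/4AP 8 h. Sat1, a polyamine acetyltransferase (2.77 against 1.30 ± 0.20), Gipr (2.35 against 0.65 ± 0.16), the dendritic protein Map2 (1.99 against 0.39 ± 0.15) and Rasd2 (1.23 against -0.41 ± 0.21) were higher than with 4AP. The connective tissue factor Ccn2 (-2.07 against 0.27 ± 0.22), the caveolar protein Cav1 (-1.83 against 0.19 ± 0.06), Ccdc80 (-0.87 against 1.21 ± 0.14) and Fbln5 (-0.68 against 1.34 ± 0.14) were lower. List medians over DMSO in this sample were -0.58 for proliferation, -0.34 for astrocyte, 0.03 for oligodendrocyte, 0.19 for microglia and -0.05 for endothelial, mural and fibroblast markers, and 0.37 for pan-neuronal markers. Across genes its ratios correlated at 0.77 with those of nifedipine and at 0.61, 0.65 and 0.68 with the Bic/4AP 8 h replicates. With 1 sample, a difference in culture or processing cannot be told apart from an effect of 4AP.

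In the limma test 30 features were higher and 259 lower than in Bic/4AP 8 h. Camera called 5 lists higher and 4 lower. Higher were pan-neuronal markers (2 and 0 of 24, 3 and 0, 0.0029) and neuropeptides (2 and 0 of 32, 4 and 1, 0.013), and also microglia markers (0 and 0 of 18, 0 and 0, 0.014), cholesterol and fatty acid genes (0 and 1 of 27, 6 and 1, 0.016) and oxidative phosphorylation (0 and 0 of 36, 0 and 0, 0.022). Lower were heat shock (0 and 1 of 38, 3 and 11, 0.011), endothelial, mural and fibroblast markers (0 and 2 of 16, 1 and 6, 0.011), astrocyte markers (0 and 2 of 21, 2 and 5, 0.013) and proliferation (0 and 0 of 20, 0 and 0, 0.014). Each of these 9 lists had an adjusted p of 0.7 with an estimated correlation. Microglia markers were not called without replicate 2 (0.07), without replicate 3 (0.14) and under 4 other settings (0.065 to 0.17). Oxidative phosphorylation was not called without replicate 2 (0.16), in the first file alone (0.18) and with plain subtraction (0.16). The call of neuropeptides was lost with scaled ratios (0.69) and in the second file alone (0.084). That of cholesterol genes was lost in the second file alone (0.073) and with plain subtraction (0.07), and that of heat shock was lost with median centring (0.14). Proliferation was not called in the authors' deposited table (0.25) and over the probes found in all samples (0.058), nor were astrocytes over these probes (0.057), with median centring (0.31) and with plain subtraction (0.11). The 289 features became 2479 without replicate 1 and 0 without replicate 2, without replicate 3, with either background subtraction, with scaled ratios and in the authors' deposited table.

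The 2 h sample asked how early the response appears. Bdnf (4.48), Egr4 (3.65), Npas4 (3.51), Nr4a3 (2.77), Scg2 (2.75), Penk (2.65), Junb (2.64) and Arc (2.16) were high over the 2 h DMSO control. The immediate early factors had a median of 0.57, against 1.37 at 8 h, and camera called the list lower than at 8 h (0 and 0 of 29, 0 and 6, 0.0027, and adjusted p = 0.72 with an estimated correlation), with the sign turned under scaled ratios (0.5). Lower than at 8 h were Gprc5a (1.03 against 5.33 ± 0.40), Porf1 (0.73 against 3.65 ± 0.25), the galectin Lgals9 (0.39 against 3.22 ± 0.32), the ephrin receptor Epha7 (-0.07 against 2.16 ± 0.16) and Gem (0.39, with 8 h at least 9.18-fold). Gucy1a1 stood at -0.20 against -1.70 ± 0.07, a difference that was not called without replicate 2 (adjusted p = 0.072 in limma). Of 37 effectors 3 were lower than at 8 h and 0 higher (6 and 0 adjusted over the list alone, camera adjusted p = 8.6e-10, adjusted p = 0.7 with an estimated correlation, and 0.068 with scaled ratios). Camera also called lower neuropeptides (0 and 0 of 32, 1 and 6, 1.2e-06), presynaptic genes (0 and 1 of 41, 0 and 6, 0.00049), MAP kinase phosphatases (0 and 0 of 25, 0 and 3, 0.0074), heat shock (0 and 0 of 38, 0 and 0, 0.027) and growth factors (0 and 0 of 30, 1 and 3, 0.05 after rounding). It called cholesterol and fatty acid genes higher (0 and 0 of 27, 0 and 0, 0.015). These 6 had an adjusted p of 0.7 or 0.72 with an estimated correlation. Heat shock was not called without replicate 2 (0.26), without replicate 3 (0.16) and under 8 other settings (0.053 to 0.17). Growth factors were not called without replicate 1 (0.084) and under 5 other settings (0.11 to 0.56). The call of cholesterol genes was lost without replicate 1 (0.13) and under 2 other settings (0.074 and 0.078), and that of phosphatases under 3 settings (0.072 to 0.39). In all, 2 features were higher and 21 lower than at 8 h in the limma test, 1235 without replicate 1, 22 without replicate 2, 0 without replicate 3, 0 with either background subtraction and 1 in the authors' deposited table.

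The pulse sample asked what remains 6 h after removal. Over its own DMSO control Ccl2 (4.68), Vgf (2.88), Penk (2.20), Scg2 (1.90), Bdnf (1.74), Arc (1.62) and Egr1 (1.51) were high, and Gprc5a at least 2.95-fold, while Crh stood at 0.04, Rgs2 at -0.14 and Inhba at -0.12. The stress enzyme Hmox1 (3.78), the actin-binding protein Flnc (3.59), Anxa1 (3.11), Anxa2 (2.93) and Akap12 (2.87) were high where Bic/4AP 8 h gave 0.28 ± 0.35, 0.04 ± 0.20, 0.15 ± 0.39, -0.33 ± 0.53 and -0.18 ± 0.48. The neurofilament Nefm stood at -2.47, the GABA-A receptor subunit Gabra5 at -2.16, Snap25 at -1.66 and Nefl at -1.48. List medians over DMSO, which were not tested, were -1.01 for pan-neuronal markers, -0.46 for presynaptic, -0.44 for GABA and -0.13 for potassium channel genes.

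Against Bic/4AP 8 h, 456 features were higher and 852 lower after the pulse. Pan-neuronal markers were lower for 16 of 24 genes and higher for 0 (20 and 0 adjusted over the list alone, camera adjusted p = 1.2e-16). Presynaptic genes were lower for 17 of 41 and higher for 1 (23 and 2 adjusted over the list alone, 4.7e-13), calcium genes lower for 17 of 53 (24 lower and 3 higher adjusted over the list alone, 3.4e-07), GABA genes for 8 of 27 (12 adjusted over the list alone, 4.5e-06) and sodium channels for 4 of 10 (4 adjusted over the list alone, 0.0011). With an estimated correlation each of these 5 lists had an adjusted p of 0.26. Fry gave 0.026 for the pan-neuronal, presynaptic, GABA and sodium channel lists and 0.031 for the calcium list. The pan-neuronal list shares members with the presynaptic, GABA and calcium lists, so their calls are not separate findings. Camera called lower also neuropeptides (1 and 14 of 32, 2 and 22, 2.1e-10), the cytoskeleton (0 and 14 of 39, 1 and 19, 1.1e-08), glutamate receptors (0 and 5 of 39, 1 and 17, 3.5e-08), effectors (4 and 11 of 37, 4 and 17, 9.7e-06) and immediate early factors (3 and 9 of 29, 3 and 13, 0.00091). Lower with a larger p were glycolysis (0 and 1 of 27, 0 and 3, 0.0061), growth factors (1 and 6 of 30, 2 and 9, 0.0062), MAP kinase phosphatases (0 and 3 of 25, 1 and 7, 0.0069), potassium channels (0 and 5 of 43, 0 and 8, 0.028), the clock (1 and 2 of 16, 2 and 6, 0.041) and oxidative phosphorylation (0 and 0 of 36, 0 and 0, 0.048). Ribosomal proteins were called higher (0 and 0 of 63, 0 and 0, 0.011). These 12 had an adjusted p of 0.26 to 0.66 with an estimated correlation. Oxidative phosphorylation was not called without replicate 1 (0.48), replicate 2 (0.068) or replicate 3 (0.24) and under 7 other settings (0.052 to 0.53), with the sign turned under median centring (0.78). Ribosomal proteins were not called without replicate 2 (0.15) and with plain subtraction (0.067). The clock was not called under 5 settings (0.061 to 0.14), potassium channels under 4 (0.05 to 0.23) and phosphatases over the probes found in all samples (0.077). In the same sample the medians over DMSO were 0.03 for astrocyte, -0.01 for oligodendrocyte, 0.08 for microglia and 0.21 for endothelial, mural and fibroblast markers, and 0.31 for proliferation. The total of 1308 became 4275 without replicate 1, 654 without replicate 2, 24 without replicate 3, 594 in the authors' deposited table, 64 with a common floor and offset and 0 with plain subtraction.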

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

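Of the tests below, those of spike-in compression, of unswapped files, of a block, of a wrong sample, of the share of neurons, of the array direction, of noise with EGTA and of the size of its differences with a common offset were chosen only after the result was seen.

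Genes raised by Bic/4AP 8 h had a median log2 ratio of 0.000979 with TTX and of 0.0253 with MK801 and nifedipine together, against 0.466 to 0.547 in held-out Bic/4AP samples. The spike-in spots argue against compressed ratios on these arrays, since their ratios were 99.4% and 86.5% of the Bic/4AP 8 h mean (1.56 ± 0.0872, SD, n = 3), and against files that cancel for want of a dye swap, since 8 of 8 spike-in pairs changed sign. A block of the response by these agents may account for the pattern, but the medians, the higher of them 0.0253, are the pattern itself and no separate test of it. A wrong sample, such as control RNA in both channels, cannot be told apart from a block, because the files of a sample shared little beyond their dye profile (r across genes of 0.2 at most) and each condition has 1 sample.

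Pan-neuronal markers had a median of -1.01 after the 2 h pulse. The background, normalization and file settings do not account for it, as the median lay between -1.22 and -0.902 under each of those run, nor do arrays read the other way round than those of Bic/4AP 8 h, as the 12 genes with the largest rise under Bic/4AP 8 h had a median of 0.966. A lower share of neurons, which would raise the markers of every other cell type alike, cannot be told apart from a change within neurons, because the lists of these types differed with a permutation p of 0.032 over all their genes but of 0.13 over those above background, where their means were 0.07 ± 0.12 for 12 astrocyte, -0.01 ± 0.06 for 11 oligodendrocyte, 0.32 ± 0.16 for 9 microglia and 0.73 ± 0.40 for 7 endothelial, mural and fibroblast genes (SE over genes). Both permutations shuffled genes among the lists within 1 sample, so they count genes as independent and cannot speak for other cultures. A change within neurons may account for the pattern too and was not tested. With 1 sample, a culture that differed before treatment stays open too.

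With EGTA 2488 features differed from Bic/4AP 8 h, of which 607 raised genes were lower and 352 lowered genes higher, as in a missing response, 45 raised genes were higher and 12 lowered genes lower, against it, and 576 lower and 896 higher features had not been called in Bic/4AP 8 h. Of as many genes chosen on the first file, 79.7% differed from Bic/4AP 8 h the same way in the second. This share cannot exclude noise of single arrays, because the same Bic/4AP 8 h mean was subtracted from both files. A missing response alone would then give equal signs. Without that mean, the ratios of the 2 EGTA files over DMSO correlated at 0.41 across all features, so they were not noise alone. Variation between samples would repeat between files and stays open, as the Bic/4AP 8 h samples gave 84.8%, 80.9% and 54.2%. Whether the smaller effective offset of these arrays made the differences was not settled by their size. With a common floor and offset the differences of the 1472 features outside the response had a median of 0.822 in place of 0.815, or 101%. The common offset of 50 lies close to the mean of 35 that already acted with EGTA, so the EGTA ratios could hardly change. Whether offsets made so many pass the test cannot be told apart from an effect of EGTA, because calls were 1.72 times as frequent in the brightest as in the dimmest of 4 equal classes of intensity but 2.03 to 3.96 times in the other conditions with at least 100 calls, so that more bright than dim calls do not exclude it, and because with a common floor and offset 0 of the 2488 were called, at a median difference of 0.907 with a standard error of 0.194 in place of 0.861 with 0.144 (the larger error and fewer prior degrees of freedom, 2.84 in place of 3.95, ended the calls, as the same values gave 3476 with the original ones). An effect of calcium chelation on features outside the response may account for them, as a hypothesis that 1 sample cannot test.

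For genes changed by Bic/4AP 8 h, 3 samples allow 4 sign splits, too few for a share under 0.05. The real split called 3139 features, the highest other split 0, and 1 split reached the real count. Turning the sign of 1 sample widens the spread of every gene that moved alike in the 3. Few calls in the other splits thus follow from the construction and say little about chance.

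The limma test of the difference itself found 23 features whose response differed between 2 h and 8 h of Bic/4AP, among them Gprc5a, Gem, Porf1, Lgals9, Epha7 and Gucy1a1. Outside the comparisons, 13 probes followed the orientation of the spike-in mix, among them Rps6ka5, Golga1, Il9, Or1e23, Or2d3c, Or4c120 and Or1j10. The spike-in spots Y5 to Y8 changed sign between the files in 44 of 44 pairs of spot and sample, with a mean absolute log2 ratio of 1.35 to 1.9 per sample.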

How the results depend on the processing

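The common floor and offset, the median foreground, the dye term and the exclusion of probes that follow the spike-in mix were chosen only after the result was seen. At the median the red foreground was 6.69 and the green foreground 4.64 times the background, and genes not above it have only bounds. None of the 34 genes named and of the 9 lists called for Bic/4AP 8 h against DMSO turned its direction under the alternatives that recompute them, while medians close to 0 with TTX, with MK801 and nifedipine together and after the pulse took either sign. Of these single genes, 598 values kept their side of the threshold, 39 lost it and 1 gained it, the last being Npy with files as arrays (adjusted p = 0.0023). Of the list tests against DMSO 506 kept their side, 17 lost it and 23 gained it. Where a replicate was left out, values were missing or files were taken as arrays, the test itself changed from camera to cameraPR. Of the counts 121 stayed within 1.5 times and 123 did not, and of the medians 210 moved by less than the spread of held-out samples and 94 by more. Plain subtraction ended 19 of 33 named calls, leaving out replicate 3 ended 10, the common floor and offset 6, and median centring, the trended prior, the authors' deposited table and leaving out replicate 2 ended 1 each. For the other comparisons and for called members of lists, 296 called differences of named genes gave 5453 values, of which 4327 kept their call, 1122 lost it and 4 turned direction without passing the test. Those were Pcdh18 with MK801, at -0.57 in the first file alone and -0.44 with the median foreground, Kcnmb3 with MK801 at -0.17 and LOC56764 with TTX at -0.26, both in the first file alone. Of 1520 values of 80 called lists 1381 kept their call, 137 lost it and 2 turned without passing, immediate early factors at 2 h with scaled ratios (adjusted p = 0.5) and oxidative phosphorylation after the pulse with median centring (0.78). Most losses of genes came with plain subtraction (286), without replicate 3 (251) and with the common floor and offset (239), and the largest numbers of lists were lost with plain subtraction (23), over the probes found in all samples (19), in the authors' deposited table (18), without replicate 2 (13) and with scaled ratios (12). Of 69 values over DMSO, named for more than 2-fold in both files of a single sample, none changed sign in 1246 values, and 142 moved by more than the gene's SD in Bic/4AP 8 h. Taking the median of several spots changed no count, since most probes have a single spot. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Unless a setting's construction shows it, as with a threshold or fewer samples, the cause was not tested.

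Of the calls against DMSO 59.5% were higher, 91.3% under plain subtraction, 73.5% with the common floor and offset, 88.1% without replicate 3, 88.9% at 2-fold and 94.9% with no model. With the other file order, which the rise of immediate early genes argues against, these would be the shares lower. Held-out medians of raised and lowered genes, 0.513 and -0.36, were 2.08 and -1.19 under plain subtraction, 1.17 and -0.662 with the common floor and offset and 0.697 and -0.475 in the authors' deposited table, so that medians there compare only within their setting. The 2 files of a sample had a consensus correlation of 0.0023, and of 0.16 with a dye term, so fits with files as arrays count them nearly as separate replicates. The lists in these sentences are those of Bic/4AP 8 h against DMSO, with adjusted p, and differing features are counted against Bic/4AP 8 h unless 2 agents are named. At an adjusted p under 0.05 with at least a 2-fold change, there were 345 higher and 43 lower against DMSO and differing features numbering 836 for EGTA and 712 after the pulse. At an adjusted p under 0.10, there were 2173 lower against DMSO and differing features numbering 1028 for Bic, 447 for TTX, 83 for MK801, 3 for nifedipine, 437 for MK801 and nifedipine together, 4308 for EGTA, 169 at 2 h, 2322 after the pulse and 32 between MK801 and nifedipine. Requiring 2-fold in all 6 files and no model, there were 185 higher and 10 lower against DMSO. With no background correction, the counts of differing features were 16 for MK801, 1601 for EGTA and 12 between MK801 and nifedipine. Under plain background subtraction, there were 116 higher and 11 lower against DMSO and differing features numbering 0 for Bic, TTX, MK801, nifedipine, MK801 and nifedipine together, EGTA, 2 h and the pulse. Medians of raised genes were 2.12 for Bic, -0.0719 for TTX, 0.809 for MK801, 1.63 for nifedipine, 0.508 at 2 h and -0.041 after the pulse, with lowered genes at -1.45 for Bic, -0.106 for TTX, -0.892 for MK801, -1.6 for nifedipine, -0.0318 for MK801 and nifedipine together, -0.362 for EGTA, -0.316 at 2 h and -0.862 after the pulse. CameraPR gave list p values of 0.036 for glutamate receptors and 0.047 for pan-neuronal markers. Local background subtraction with a common floor and offset gave 707 higher and 255 lower against DMSO and differing features numbering 0 for Bic, TTX, MK801, nifedipine, MK801 and nifedipine together, EGTA and 2 h and 64 after the pulse. For raised genes the medians became 1.07 for Bic, 0.393 for MK801, 0.851 for nifedipine and 0.186 at 2 h, with lowered genes at -0.675 for Bic, -0.378 for MK801, -0.726 for nifedipine, -0.126 for EGTA and -0.324 after the pulse. The median foreground gave differing features numbering 12 between MK801 and nifedipine. In camera, list p values were 0.037 for cytoskeleton and 0.05 for pan-neuronal markers.

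Median centring within an array put the medians of lowered genes at -0.486 for Bic, -0.515 for nifedipine, 0.059 for MK801 and nifedipine together and -0.0734 for EGTA. The camera p values of lists were 0.047 for cytoskeleton and 0.047 for oxidative phosphorylation. Global loess gave differing features numbering 2 between MK801 and nifedipine. The camera p value of the cytoskeleton was 0.026. Scaling the ratios between arrays gave differing features numbering 0 for Bic, 422 for TTX, 53 for MK801, 3 for nifedipine, 580 for EGTA, 87 at 2 h and 22 between MK801 and nifedipine. Raised genes had medians of 0.444 for Bic, 0.385 for nifedipine and 0.15 at 2 h, with lowered genes at -0.328 for Bic, -0.301 for MK801 and -0.404 for nifedipine. The authors' deposited table gave 1138 higher and 759 lower against DMSO and differing features numbering 0 for Bic, 58 for TTX, 1 for MK801 and 2 h, 42 for MK801 and nifedipine together, 686 for EGTA and 594 after the pulse. Medians of raised genes were 0.85 for Bic, 0.356 for MK801, 0.693 for nifedipine, 0.116 for EGTA and 0.155 at 2 h, with lowered genes at -0.541 for Bic, -0.32 for MK801 and -0.601 for nifedipine. In cameraPR, list p values were 0.039 for calcium genes and 0.063 for heat shock. No filter on dim probes gave camera list p values of 0.046 for cytoskeleton and 0.047 for pan-neuronal markers. Keeping only probes found in all samples gave differing features numbering 42 for MK801, 0 for nifedipine, 1577 for EGTA, 60 at 2 h and 12 between MK801 and nifedipine. The median of raised genes became 0.533 for Bic. The camera p value of the circadian clock was 0.11. The first file alone gave differing features numbering 158 for Bic, 41 for MK801, 14 for nifedipine, 326 for MK801 and nifedipine together, 39 at 2 h and 26 between MK801 and nifedipine. Raised genes had medians of 0.658 for Bic, 0.512 for nifedipine and 0.151 at 2 h, with lowered genes at -0.0246 for TTX, -0.294 for MK801, -0.0319 for MK801 and nifedipine together, -0.094 for EGTA, -0.138 at 2 h and -0.25 after the pulse. Camera gave list p values of 0.026 for glycolysis and 0.013 for pan-neuronal markers. The second file alone gave differing features numbering 81 for Bic, 15 for nifedipine, 51 at 2 h and 33 between MK801 and nifedipine. Medians of raised genes were 0.282 for MK801, 0.0709 for MK801 and nifedipine together, 0.171 for EGTA, 0.17 at 2 h and 0.123 after the pulse, with lowered genes at -0.126 for EGTA. In camera, list p values were 0.029 for cytoskeleton and 0.029 for oxidative phosphorylation. Files as arrays with the sample as a random block gave 3546 higher and 3231 lower against DMSO and differing features numbering 3347 for Bic, 2461 for TTX, 1281 for MK801, 1287 for nifedipine, 2425 for MK801 and nifedipine together, 6043 for EGTA, 1528 at 2 h, 4620 after the pulse and 543 between MK801 and nifedipine. For raised genes the medians became 0.337 for Bic, 0.132 for MK801, 0.27 for nifedipine and 0.0626 at 2 h, with lowered genes at -0.283 for Bic, -0.157 for MK801, -0.31 for nifedipine and -0.124 after the pulse. The cameraPR p values of lists were 0.05 for calcium genes and 0.0015 for pan-neuronal markers. Files as arrays with a dye term besides gave 3461 higher and 3142 lower against DMSO and differing features numbering 3077 for Bic, 2258 for TTX, 1062 for MK801, 1068 for nifedipine, 2206 for MK801 and nifedipine together, 5982 for EGTA, 1301 at 2 h, 4435 after the pulse and 467 between MK801 and nifedipine. A robust prior with an intensity trend gave differing features numbering 3 for nifedipine and 27 between MK801 and nifedipine. With an estimated correlation 8 of the 9 lists that camera called had an adjusted p of 0.47 and presynaptic genes 0.53. This check had 2 residual degrees of freedom and could hardly call any list, so it does not undo those calls. Fry gave 0.09 for endothelial, mural and fibroblast markers, 0.075 for heat shock, 0.068 for presynaptic genes and 0.041 for glutamate receptors.

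Leaving out 1 Bic/4AP 8 h sample at a time gave 393 to 2641 features higher and 53 to 2193 lower than DMSO, with the fewest without replicate 3 and the most without replicate 1. Differing features ranged from 0 to 2479 for Bic, 0 to 1911 for TTX, 0 to 970 for MK801, 0 to 1293 for nifedipine, 0 to 1980 for MK801 and nifedipine together, 25 to 5479 for EGTA, 0 to 1235 at 2 h, 24 to 4275 after the pulse and 0 to 643 between MK801 and nifedipine. Of raised genes, medians ranged from 0.467 to 1.39 for Bic, -0.0121 to 0.00123 for TTX, 0.149 to 0.438 for MK801, 0.327 to 1.11 for nifedipine, 0.0135 to 0.0283 for MK801 and nifedipine together, 0.0509 to 0.0681 for EGTA, 0.0784 to 0.313 at 2 h and 0.0191 to 0.054 after the pulse. Of lowered genes, they ranged from -0.81 to -0.37 for Bic, 0.0181 to 0.0332 for TTX, -0.459 to -0.181 for MK801, -0.912 to -0.32 for nifedipine, -0.0185 to 0.0148 for MK801 and nifedipine together, -0.193 to -0.0674 for EGTA, -0.216 to -0.0441 at 2 h and -0.604 to -0.0971 after the pulse. List p values, here from cameraPR, ranged from 0.0043 to 0.5 for the cytoskeleton, 0.00012 to 0.99 for microglia, 3.3e-05 to 0.13 for pan-neuronal markers, 0.00032 to 0.5 for proliferation, 0.00051 to 0.13 for endothelial, mural and fibroblast markers and 0.0039 to 0.11 for heat shock.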

Other observations

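Txnip, which encodes a thioredoxin-interacting protein, stood at -1.70 over DMSO in Bic alone, -1.94 with MK801, -2.05 with nifedipine and -0.94 after the pulse, at 1.80 with EGTA, and at -0.59 ± 0.59 (SD, n = 3, adjusted p = 0.12 in limma) in Bic/4AP 8 h. Bic alone, MK801 and nifedipine were also the single samples with Y5 higher in red of the first file, so processing cannot be told apart from treatment there. Ccl2 stood at 5.14 with nifedipine and 4.68 after the pulse, the highest of its values among the conditions, and at 1.30 with EGTA. Egr1 stood at 1.90 with EGTA, against 2.15 ± 0.43 in Bic/4AP 8 h, while the median of its list of immediate early transcription factors was 0.21 there.

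Genes of cholesterol and fatty acid synthesis had a median of -0.38 over DMSO after the pulse, where 5 of 27 were lower than in Bic/4AP 8 h and 0 higher (7 and 0 adjusted over the list alone, camera adjusted p = 4.4e-05, and adjusted p = 0.26 with an estimated correlation). Of the proliferation list 3 of 20 genes were higher after the pulse than in Bic/4AP 8 h, with differences of 1.18 for Mcm6, 1.07 for Mcm7 and 1.00 for Mcm5 (camera adjusted p = 0.0013, adjusted p = 0.47 with an estimated correlation, 0.053 in the authors' deposited table and 0.051 over the probes found in all samples). In Bic alone the cell cycle genes Cdk1 and Mki67 stood at -1.72 and -1.49 over DMSO, with 0 of 20 called against Bic/4AP 8 h.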
